A study of Sus scrofa with 56 samples.

How the data were processed

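Peripheral blood mononuclear cells of 28 sows (Sus scrofa) were sampled on day 98 of gestation and day 11 of lactation, with 56 libraries in all. Per the labels' protocols, RNA was isolated with a NucleoSpin RNA kit and 500 ng of total RNA went into QIAseq Stranded mRNA libraries with 12 amplification cycles. Genome build Sscrofa11.1, R 4.1.2 and DESeq2 are named in the submitters' processing notes, and the aligner, the quantifier and the annotation version are not given in the sources used here.

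There was 1 file per library, with 24358 Ensembl gene IDs in each. Per the file headers, the authors deposited an estimated count per gene, not normalised, together with TPM from their own quantification. The estimated counts were rounded to whole numbers (4.61% of them were not whole), and the deposited TPM values were not used in any test. Symbols came from a gene name table and matched 14690 IDs (60.3%). Coordinates are gene spans from the NCBI RefSeq annotation of Sscrofa11.1, the build named in the submitters' notes, matched by symbol and counted from 1, so exons and untranslated regions are not distinguished. How reads shared between paralogs, such as haemoglobin or ribosomal protein genes and their copies, were assigned is not given in the sources used here, and values of such genes are uncertain to that extent.

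Totals ran from 18096881 to 25302994 counts per library, so a gene at 1 CPM stands for about 18.1 to 25.3 counts in a library. The 10 most abundant genes took 5.96% to 28.6% of the counts. The counts within each group differed by more than sampling noise in all 75 pairs of libraries of a group (chi-square per degree of freedom 18.5 to 605 over genes with at least 20 counts), so no library was counted as a repeat of another. The labels give each sow's ear tag. Libraries of 26 pairs come from the same sow and replicate at both stages, and 2 sows, T82133 and T82157 by their tags, have an L11 library in each replicate, labelled intermediate in R1 and dominant in R2. These repeat libraries are not separate animals, so the L11 tests of single genes were also run without them. The L11 tests of gene lists were not.

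Differences were tested with edgeR 4.0.16 (TMM scaling, filterByExpr on the factor tested, glmQLFit and glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. Housing was fitted with parity as covariate, and parity and dominance with housing, within each stage. Dominance was tested as dominant minus subordinate with the intermediate sows in the fit. Stage was fitted with a term per sow and replicate over 52 libraries. The interactions of stage with housing, parity and dominance were each tested in a separate fit of this kind, not adjusted for each other. No method text stated the model used by the submitters. The p-values are 2-sided.

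Fixed before the data were examined were the groups, the tests, the alternatives, 27 gene lists and the rule for naming genes. The lists covered B cell, plasma cell, T cell, naive and central memory T cell, regulatory and activated T cell, gamma delta T cell, cytotoxic and NK cell, monocyte, dendritic cell, granulocyte, platelet and erythroid genes, interferon-stimulated, inflammatory cytokine and NF-kB, glucocorticoid-responsive, immediate early and cell cycle genes, MHC class II, ribosomal protein, nuclear oxidative phosphorylation, mitochondrially encoded, heat shock and chaperone and endoplasmic reticulum stress genes, and glycolysis and hypoxia, cholesterol synthesis and lipid metabolism, complement and hormone receptor genes. Each was tested with limma 3.58.1 camera on log2 CPM (prior count 2, preset correlation 0.01) with the design of its comparison, adjusted over the 27 lists, and again with an estimated correlation and with fry. The rule named, among called genes with a symbol and a mean log2 CPM of at least 1, the 8 largest rises and 8 largest falls, and up to 3 called members with the smallest p of each list with at least 2 called, to about 30 genes. Where 16 or fewer genes with a symbol were called all were named, and where none was called the 3 with the smallest p. Further members of the lists are given as examples of their list. Genes of the comparison of R2 with R1 and a list of stromal cell genes were chosen after the values were seen.

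The alternatives were DESeq2 1.42.0, its size factors in the edgeR fit, no filter and a stricter filter (at least 1 CPM in at least 50% of the libraries), a threshold of 0.1, the replicate as a block, all 3 factors in the fit, and limma voom over both stages with the sow as a random block. Others were the repeat libraries or the intermediate sows left out, the unpaired fit and the fit within R1 or R2 for stage, and each sow left out in turn. Chosen after the data were seen were all 3 factors together with the replicate block, the fits without the library of high C1QA, a replicate by stage term and HBB as a covariate. The labels say that a number marks an experimental replicate, so the numbers mark sets of libraries and do not pair single samples. Deviations from the means of each stage, housing and parity group correlated at 0.16 on average between libraries of different groups with the same number. Between those with different numbers they correlated at −0.16. Each such group holds libraries of both numbers, so any difference between R1 and R2 gives near opposite values. The values show such a difference and not a pairing.

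The fits were tested on simulated counts with the real means, library sizes and dispersions and 200 changed genes. Of 100 genes changed by 1 on the log2 scale, 89.9% that passed the filter were recovered for housing at G98, 89.9% for parity at G98, 74.7% for dominance at G98, 95.9% for housing at L11, 87.8% for parity at L11, 78.6% for dominance at L11, 97.0% for stage and 83.0% for the stage by parity interaction. Of 100 genes changed by 0.5, 27.6% (dominance at L11) to 89.0% (stage) were recovered, and 1.57% to 4.58% of the calls were false. Each simulated gene was drawn on its own around a single mean, without effects of replicate or sow and without correlation between genes. The real libraries have such structure, so these rates may not hold for them.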

Results

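RNA was sequenced from peripheral blood mononuclear cells, the lymphocytes, monocytes and dendritic cells of circulating blood, of 28 sows that had farrowed before. Each stage gave 28 libraries, taken on day 98 of gestation (G98) and on day 11 of lactation (L11). The sows had been kept in a conventional or an enriched housing environment, belonged to a low parity group (LP, in gestation 2 or 3) or a high parity group (HP, in gestation 4 or later), and were ranked as dominant, intermediate or subordinate. At G98 there were 14 conventional and 14 enriched, 15 LP and 13 HP, and 8 subordinate, 11 intermediate and 9 dominant libraries, and at L11 there were 14 and 14, 14 and 14, and 8, 9 and 11. The work was run in 2 experimental replicates, R1 and R2, with 14 libraries each at each stage. The total estimated count was 18764208 to 24894793 per library at G98 and 18096881 to 25302994 at L11, and 14276 to 14825 genes had a count above 0.

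Gene levels below are TMM-scaled CPM as mean ± SD, and fold changes are log2 with their standard error (SE) from edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p. In the 500 most variable genes, the first principal component held 22% of the variance, of which R1 against R2 explained 58.7% and stage 27.6%. Between R2 and R1, 4993 genes differed at G98 and 5322 at L11. Housing and parity were spread over both replicates, so this difference does not follow those groups. At G98 6 of 9 dominant and 3 of 8 subordinate libraries were from R1.

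The first comparison asked how the blood cell transcriptome changed from late gestation to lactation in the same animals, with 26 pairs of libraries from a single sow and replicate. Red cell transcripts fell between G98 and L11. The haemoglobin subunit gene HBB went from 20160 ± 35570 to 3365 ± 7052 CPM (n = 26 each, log2 fold change −2.58, SE 0.62, adjusted p = 0.000789, higher at L11 in 4 of 26 pairs). The red cell anion exchanger SLC4A1 went from 10.1 ± 16.9 to 0.981 ± 1.70 CPM (−3.22, SE 0.38, adjusted p = 4.91e-08). The neutrophil-attracting chemokine CXCL2 went from 26.97 ± 27.7 to 96.4 ± 100.8 CPM (1.94, SE 0.25, adjusted p = 1.99e-07, higher in 24 of 26 pairs). The anti-inflammatory cytokine IL10 went from 4.40 ± 2.24 to 15.0 ± 11.3 CPM (1.59, SE 0.16, adjusted p = 2.30e-09, higher in 25 of 26). Many genes of the mitochondrial respiratory chain and of ribosomes rose by smaller folds. The complex I subunit gene NDUFB1 went from 6.40 ± 1.71 to 14.9 ± 2.87 CPM (1.24, SE 0.09, adjusted p = 1.05e-11, higher in 26 of 26). Genes of naive and central memory T cells fell, among them the chromatin organiser SATB1, from 145 ± 19.5 to 110 ± 17.2 CPM (−0.41, SE 0.03, adjusted p = 4.91e-11, higher in 0 of 26).

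In all, 6990 of 12349 genes tested changed, 3502 upward and 3488 downward, and 179 of them by more than 2-fold (99 up, 80 down). The median size of a called change was 0.31 on the log2 scale. Besides CXCL2 and IL10, the largest rises in genes with a mean log2 CPM of at least 1 were those of the cytokine IL1A (log2 fold change 1.90, SE 0.48, higher in 16 of 26 pairs), the gelatinase MMP9 (1.90, SE 0.25, 25 of 26) and the collagen COL3A1 (1.69, SE 0.71, adjusted p = 0.0424, 18 of 26). They were followed by the complement subunit C1QA (1.68, SE 0.48), the neutrophil chemoattractant CXCL8 (1.65, SE 0.23) and the calcium-binding monocyte protein S100A8 (1.61, SE 0.25). IL1A averaged 0.149 CPM at G98 and 0.130 CPM at L11 in R1, where it did not rise. C1QA went from 0.435 ± 0.473 to 19.2 ± 92.3 CPM. The largest falls were in genes of the red cell lineage: carbonic anhydrase CA1 (−3.83, SE 0.47), SLC4A1, the membrane skeleton protein DMTN (−2.70, SE 0.42), the haemoglobin chaperone AHSP (−2.64, SE 0.54), HBB and the haemoglobin subunit HBM (−2.52, SE 0.53). The methyltransferase INMT (−3.32, SE 0.42) and the synuclein SNCG (−2.10, SE 0.51) fell with them. HBB (ENSSSCG00000014725) lies on chromosome 9 at 4800683 to 4801941 of Sscrofa11.1, CXCL2 (ENSSSCG00000008959) on chromosome 8 at 70157253 to 70159145, NDUFB1 (ENSSSCG00000002449) on chromosome 7 at 113652772 to 113659937 and SATB1 (ENSSSCG00000011201) on chromosome 13 at 5315985 to 5410686, all as gene spans of the RefSeq annotation.

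By gene list, the members that passed over all genes were as follows, with the count adjusted over the list alone where it differs. Of 60 measured nuclear oxidative phosphorylation genes 54 rose (55 adjusted over the list alone), with NDUFB1, NDUFA6 (0.45, SE 0.04) and the electron carrier CYCS (0.78, SE 0.08) at the smallest p. Of 48 ribosomal protein genes 37 rose (38 adjusted over the list alone), led by RPL36A (0.70, SE 0.07), RPL27 (0.69, SE 0.08) and RPS15A (0.85, SE 0.10). Of 12 genes of the mitochondrial genome 9 rose, with ND3 at 0.91 (SE 0.09), ATP6 at 0.71 (SE 0.10) and COX3 at 0.58 (SE 0.08). All 10 erythroid markers fell (median −2.22), among them the membrane protein gene EPB42 (−1.88, SE 0.31). Of 10 genes of naive and central memory T cells 8 fell, including SATB1, the quiescence factor KLF2 (−0.40, SE 0.04) and the lymph node homing receptor CCR7 (−0.44, SE 0.05). Of 13 T cell markers 7 fell (8 adjusted over the list alone), such as BCL11B at −0.84 and CD3D at −0.36, and CD3E rose by 0.17. The camera test with a preset correlation of 0.01 called these 6 lists, with adjusted p = 4.46e-13, 1.77e-08, 0.00287, 0.000626, 0.00101 and 0.0281 in that order, and none of them passed with an estimated correlation (adjusted p = 0.480 for each).

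Of 17 inflammatory cytokine and NF-kB genes 12 rose and NFKB1 and RELB fell (median 0.68, camera adjusted p = 0.00564). Of 12 glucocorticoid-responsive genes 7 rose (camera adjusted p = 0.00564), among them DDIT4 by 0.82, SGK1 by 0.82 and the clock gene PER1 by 0.71. Of 16 monocyte markers 9 rose (camera adjusted p = 0.00564), including the transcription factor CEBPB by 0.65 and the endotoxin co-receptor CD14 by 0.64, and CD163 was at −0.23 (adjusted p = 0.264). Of 12 endoplasmic reticulum stress genes 8 rose (camera adjusted p = 0.00779). Of 9 dendritic cell markers 6 rose and ZBTB46 fell, and of 8 complement genes 6 rose (7 adjusted over the list alone). Of 15 glycolysis and hypoxia genes 10 rose and PDK1 fell, and of 16 cytotoxic and NK cell genes 8 rose and EOMES fell (camera adjusted p = 0.0300 for each of the last 4). None of the 14 lists called by camera passed with an estimated correlation, each at adjusted p = 0.480 with an estimated correlation, while fry, which asks whether the members of a list move on balance in the same direction, called 22 of 27.

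The remaining 13 lists were not called by camera. Of 12 heat shock and chaperone genes 5 rose (camera adjusted p = 0.0789), led by BAG3 at 0.80. Of 10 plasma cell markers 7 rose and POU2AF1 fell (0.0925; 8 and 1 adjusted over the list alone), and of 18 cholesterol synthesis and lipid metabolism genes 3 rose and 7 fell (0.0999), the fatty acid synthase FASN by −0.53 among the latter. Of 16 immediate early genes 8 rose and 2 fell (0.117), and of 6 MHC class II genes 4 rose (0.137). Of 7 hormone receptor genes THRB rose and 4 fell (0.162), and of 6 gamma delta T cell genes 3 fell (0.162). Of 11 platelet markers 3 fell (0.182), and of 9 granulocyte markers 5 rose and 2 fell (0.243). Of 22 cell cycle genes 4 rose and 7 fell (0.381), of 12 B cell markers 1 rose and 2 fell (0.624) and of 26 interferon-stimulated genes 2 rose and 2 fell (0.624). Of 12 genes of regulatory and activated T cells 3 rose and 3 fell (0.777), and there the median of −0.07 and the mean of 0.03 differ in sign.

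The change differed between the replicates for 2576 of 12349 genes. Of 12115 genes tested in each replicate, 5219 were called within R1 and 5879 within R2, and of the 3302 called in both 3162 went the same way and 140 opposite ways. The erythroid list had a median of −3.46 within R1 and −0.81 within R2, the ribosomal protein list 0.11 and 0.62, and the nuclear oxidative phosphorylation list 0.15 and 0.65. Within R1 14 ribosomal protein genes rose and 4 fell. Of the plasma cell markers 0 rose and 2 fell within R1 (median −0.012), and 8 rose and 0 fell within R2 (0.58). The median was also below 0 in R1 and above 0 in R2 for MHC class II (−0.019 and 0.38), interferon-stimulated (−0.13 and 0.41), cholesterol synthesis and lipid metabolism (−0.24 and 0.037) and cell cycle genes (−0.12 and 0.012) and B cell markers (−0.12 and 0.067). HBB fell by 4.58 (SE 0.82) in R1 and was at −0.81 (SE 0.36, adjusted p = 0.0714) in R2. COL3A1 was at 0.48 (SE 0.79, adjusted p = 0.648) in R1 and rose by 3.02 (SE 1.00) in R2. C1QA, CD163 and S100A8 reached 471, 2000 and 775 CPM in a single L11 library from R2, of a conventional HP dominant sow, against at most 5.97, 227 and 115 CPM in the 27 other L11 libraries. Without that sow, an alternative chosen after seeing the data, 6983 genes changed, C1QA at 1.24 and S100A8 at 1.48. The erythroid markers took 3.14 ± 3.71% of the counts in R1 at G98 (n = 14), against 0.33 ± 0.29% in R2 at G98, 0.41 ± 0.88% in R1 at L11 and 0.23 ± 0.39% in R2 at L11. IL1A was at 1.11 averaged over both replicates (adjusted p = 0.0808), which ends its call, and COL3A1 was at adjusted p = 0.0779 without a single sow. The labels' codes of all 28 G98 libraries belong to a different series from those of all 28 L11 libraries, so stage and library series cannot be told apart.

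**Figure D1:**
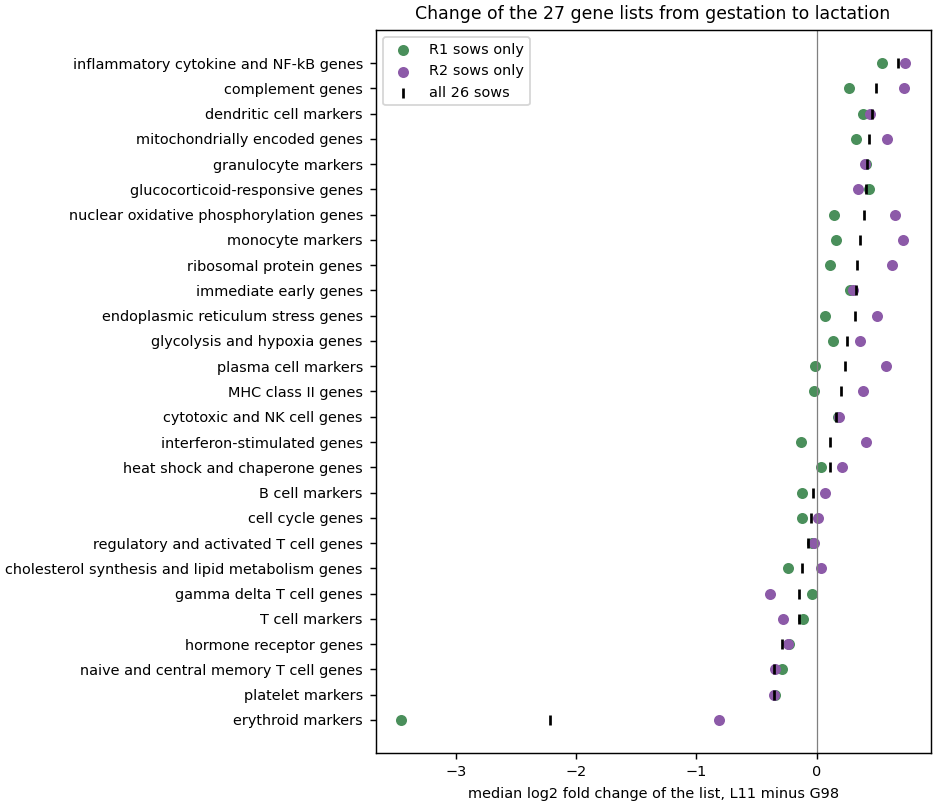
Median log2 fold change from G98 to L11 (horizontal axis) of the 27 gene lists (vertical axis), with green points from R1 sows, purple points from R2 sows and black ticks from all 26 pairs. The erythroid list has its median at −3.46 in R1 and −0.81 in R2, and the ribosomal and oxidative phosphorylation lists lie further right in R2 than in R1.

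**Figure D2:**
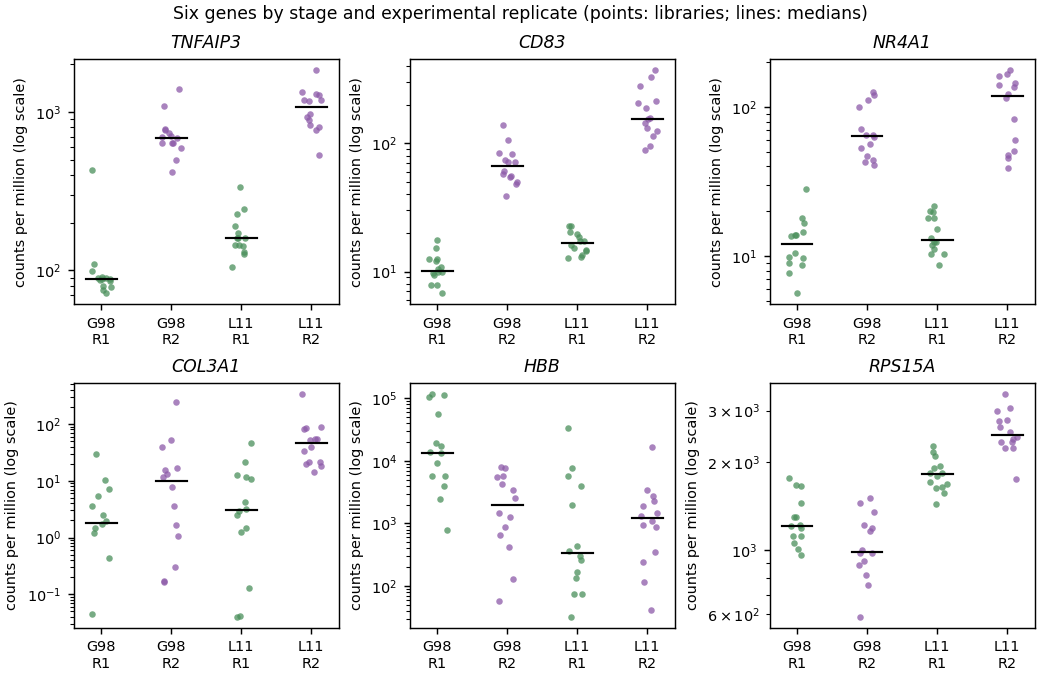
CPM on a log scale (vertical axis) of TNFAIP3, CD83, NR4A1, COL3A1, HBB and RPS15A in each library, by stage and replicate (horizontal axis, n = 14 each), with lines at the medians. CD83 averages 10.9 and 71.2 CPM in R1 and R2 at G98, and 17.1 and 186 CPM at L11.

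The next comparison asked whether the cells of older sows differed from those of younger ones at each stage. At G98, genes that mark gamma delta T cells, a lymphocyte class abundant in pig blood, were lower in HP sows. The transcription factor SOX13 was at 47.4 ± 21.8 CPM in HP (n = 13) against 104 ± 31.1 CPM in LP (n = 15; log2 fold change −1.21, SE 0.22, adjusted p = 0.00645, below the LP mean in 13 of 13 HP libraries). The kinase BLK was at 74.2 ± 20.3 against 128 ± 31.1 CPM (−0.82, SE 0.15, adjusted p = 0.00587, below the LP mean in 13 of 13). The transcription factor GATA3 was at 152 ± 27.9 against 210 ± 27.5 CPM (−0.49, SE 0.08, adjusted p = 0.00379, below the LP mean in 12 of 13). Among the genes higher in HP sows, the mannose receptor MRC1 was at 9.88 ± 4.81 against 3.94 ± 1.59 CPM (1.37, SE 0.26, adjusted p = 0.00960), and the haemoglobin scavenger receptor CD163 was at 161 ± 52.7 against 112 ± 34.1 CPM (0.65, SE 0.16, adjusted p = 0.0372). BATF3, a transcription factor of conventional dendritic cells, was at 9.50 ± 1.45 against 6.004 ± 1.49 CPM (0.64, SE 0.11, adjusted p = 0.00314).

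At G98, 180 of 12273 genes differed, 69 higher and 111 lower in HP, and 24 by more than 2-fold (2 higher, 22 lower). The gene with the smallest p was the homeobox factor CUX2, at 6.82 ± 2.24 against 14.9 ± 3.14 CPM (−1.15, SE 0.15, adjusted p = 0.000248). Other large falls were those of the acid-sensing channel ASIC4 (−1.36, SE 0.29), the sortilin family receptor SORCS2 (−1.21, SE 0.25), the transporter SLC6A17 (−1.07, SE 0.25), PAMR1 (−1.07, SE 0.27), the interleukin-9 receptor IL9R (−1.05, SE 0.22) and RHEX, a regulator of erythroid cell expansion (−1.04, SE 0.23). Other large rises were those of the adhesion receptor ADGRV1 (0.81, SE 0.16), the protease-activated receptor F2RL1 (0.75, SE 0.17), the interleukin-36 receptor IL1RL2 (0.74, SE 0.17), the splicing factor RBM20 (0.73, SE 0.15) and the membrane anchor ANK2 (0.68, SE 0.16). SOX13 (ENSSSCG00000015277) lies on chromosome 9 at 64745762 to 64780942, BLK (ENSSSCG00000027568) on chromosome 14 at 14688489 to 14745946, GATA3 (ENSSSCG00000011125) on chromosome 10 at 63367684 to 63397977 and MRC1 (ENSSSCG00000011038) on chromosome 10 at 44107926 to 44226734.

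Of the 6 measured gamma delta T cell genes, SOX13, BLK and GATA3 were lower in HP sows at G98 (1 higher and 4 lower adjusted over the list alone), with ID3 at −0.45 and IL23R at 0.36, neither of which passed over all genes. The list median was −0.47 (camera adjusted p = 0.00740, fry adjusted p = 0.0186, adjusted p = 0.476 with an estimated correlation). BLK is also the single called member of the 12 B cell markers (median −0.24, camera adjusted p = 0.00628). Camera called 9 other lists, each at a single called member or none: nuclear oxidative phosphorylation, ribosomal protein, monocyte, cytotoxic and NK cell, glycolysis and hypoxia, complement and mitochondrially encoded genes higher, and cell cycle and naive and central memory T cell genes lower. Their called members were NDUFB10 (0.20), CD163 and the T cell factor LEF1 (−0.38). With an estimated correlation none of the 11 lists passed, at adjusted p = 0.476 to 0.661 with an estimated correlation.

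At L11, 22 of 12298 genes differed between HP and LP, 2 higher and 20 lower in HP. The 14 HP libraries are from 12 sows, and without the repeat libraries of 2 of them 12 genes were called, BATF3, RHEX, ACVR2A and LZTS1 not among them and SOX13 and BLK among them. SOX13 was at 32.2 ± 11.5 CPM in HP against 71.3 ± 21.1 CPM in LP (n = 14 libraries each, −1.20, SE 0.21, adjusted p = 0.00723) and BLK at 65.0 ± 19.5 against 116 ± 25.3 CPM (−0.85, SE 0.14, adjusted p = 0.00723). IL9R (−1.23, SE 0.23), RHEX (−1.15, SE 0.23), CUX2 (−1.01, SE 0.18), the activin receptor ACVR2A (−0.93, SE 0.19), LZTS1 (−0.90, SE 0.20) and the amino acid sensing GTPase RRAGD (−0.81, SE 0.13) were also lower, and VWA5A (1.57, SE 0.29) and BATF3 (0.60, SE 0.13) were higher. Among genes lower in HP, 16 were called at both stages, of 111 and 20, against 0.18 for independent lists, and among those higher 1 was, of 69 and 2, against 0.01. Since 26 of the sow and replicate pairs are the same at both stages, this overlap is not from separate animals. The gamma delta list (median −0.38, 2 of 6 called and 3 adjusted over the list alone) was called by camera (adjusted p = 6.17e-06), by fry (adjusted p = 0.00262) and at adjusted p = 0.0311 with an estimated correlation. The list tests kept the repeat libraries and were not run without them. Of the 9 lists called by camera, the gamma delta list alone passed with an estimated correlation. The other 8 were B cell markers, erythroid markers and cholesterol synthesis and lipid metabolism genes, all lower in HP, and nuclear oxidative phosphorylation, complement, monocyte, ribosomal protein and glycolysis and hypoxia genes, all higher, at adjusted p = 0.202 to 0.744 with an estimated correlation. The library of high C1QA, CD163 and S100A8 described above, genes of the complement and monocyte lists, is from an HP sow, and without it 15 genes were called.

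**Figure D3:**
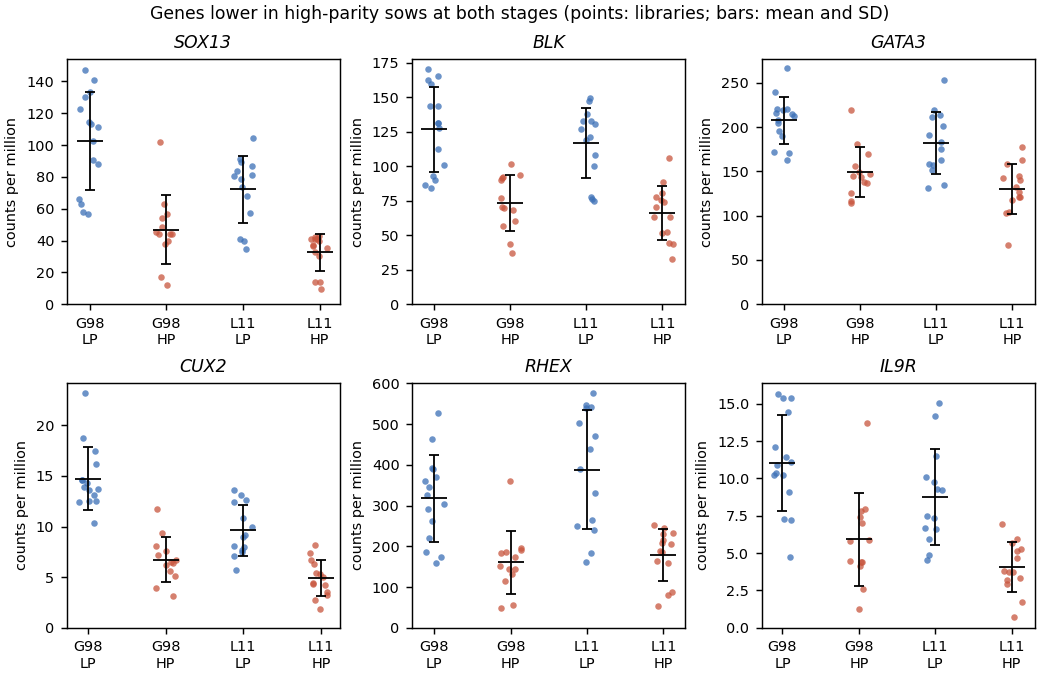
CPM (vertical axis) of SOX13, BLK, GATA3, CUX2, RHEX and IL9R in each library by stage and parity group (horizontal axis), with bars at the mean and SD. At L11 SOX13 averages 71.3 CPM in LP and 32.2 CPM in HP sows, and GATA3 at L11 does not pass over all genes (adjusted p = 0.0539) but does with the replicate as a block (adjusted p = 0.00432).

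Parity and dominance were close to nested: at G98 8 of 13 HP libraries were from dominant sows and 1 of 15 LP libraries was, and at L11 10 of 14 and 1 of 14. With dominance in the fit, 2 genes were called at G98 and 0 at L11 by edgeR (against 180 and 22 without it), and SOX13 was at −0.89 (SE 0.26, adjusted p = 0.392) and −0.93 (SE 0.26, adjusted p = 0.987). With the replicate as a block, 357 and 37 genes were called, DESeq2 called 459 and 61, and leaving out a single sow gave 52 to 581 and 7 to 42. Of the genes named, F2RL1, IL1RL2, ANK2, CD163, SLC6A17 and PAMR1 at G98 and VWA5A, BATF3, IL9R, RHEX, ACVR2A and LZTS1 at L11 lost their call without a single sow. Within R1 and R2, SOX13 was at −1.31 and −1.06 at G98 and at −1.31 and −1.08 at L11.

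The comparison of dominant with subordinate sows gave no gene past the threshold at either stage by edgeR. At G98 (9 dominant and 8 subordinate libraries) the smallest adjusted p was 0.0539, for the stress-induced SESN1 at 18.1 ± 1.91 against 14.4 ± 1.95 CPM (log2 fold change 0.42, SE 0.08). It was shared by the carboxypeptidase CPD at 73.9 ± 8.90 against 54.3 ± 7.72 CPM (0.53, SE 0.10) and the glycolytic enzyme PGAM2 at 7.70 ± 1.71 against 11.5 ± 1.88 CPM (−0.63, SE 0.12). At L11 (11 dominant and 8 subordinate libraries) the genes with the smallest p were the cell polarity gene EPB41L5 (−1.08, SE 0.19, adjusted p = 0.0777), the bicarbonate transporter SLC4A4 (−0.95, SE 0.19, adjusted p = 0.0830) and the adhesion molecule L1CAM (−0.97, SE 0.20, adjusted p = 0.0830). B cell markers had lower values in dominant sows at both stages: PAX5 was at −0.73 (SE 0.21) and −0.91 (SE 0.25) and CD79A at −0.47 (SE 0.12) and −0.46 (SE 0.11). Of the 12 measured, 7 at G98 and 9 at L11 passed as lower adjusted over the list alone, and 0 over all genes. These fits left parity out. At G98 8 of 9 dominant libraries were HP and 7 of 8 subordinate libraries LP, and at L11 10 of 11 and 7 of 8. The lists were not tested with parity in the fit, so rank and parity cannot be told apart for them.

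The B cell list was called by camera at G98 (median −0.54, adjusted p = 6.92e-08, fry 0.0237, adjusted p = 0.433 with an estimated correlation) and at L11 (median −0.76, adjusted p = 2.04e-13, fry 0.00668, adjusted p = 0.0588 with an estimated correlation). Camera also called nuclear oxidative phosphorylation, monocyte and complement genes as higher and gamma delta T cell genes as lower at both stages. At L11 it further called cytotoxic and NK cell genes and cell cycle genes as higher and mitochondrially encoded genes and erythroid markers as lower. None of these passed with an estimated correlation, at adjusted p = 0.433 to 0.875 with an estimated correlation at G98 and 0.218 to 0.658 at L11. With the replicate as a block the oxidative phosphorylation list at G98 (adjusted p = 0.0575) and the cell cycle list at L11 (0.0624) ended their calls. Endoplasmic reticulum stress genes at G98 (0.0330) and glycolysis and hypoxia (0.0131) and ribosomal protein genes (4.89e-05) at L11 gained a call as higher. Over the list alone CD163, S100A12, CEBPD and S100A8 passed as higher at L11, where CD163 was at 1.79 (SE 0.51), and the library of high CD163 is from a dominant sow. At an unadjusted p under 0.05 there were 1814 genes at G98 and 1191 at L11, DESeq2 called 218 and 59, limma voom with both stages 30 and 13, and with the replicate as a block edgeR called 0 and 3. Leaving out a single sow gave 0 to 161 and 0 to 32 genes.

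The comparison of enriched with conventional housing gave a single gene at G98. AHRR, the repressor of the aryl hydrocarbon receptor, was at 4.46 ± 1.00 CPM in enriched against 2.49 ± 0.65 CPM in conventional sows (n = 14 each, log2 fold change 0.79, SE 0.13, 1.73-fold, adjusted p = 0.0106, above the conventional mean in 14 of 14 enriched libraries). AHRR (ENSSSCG00000032843) lies on chromosome 16 at 79730920 to 79810183. It was called without each sow in turn and with the replicate as a block, and not by limma voom with both stages, which called 0 genes (adjusted p = 1.00 for AHRR). At L11 no gene was called by edgeR, DESeq2 or limma voom, with 735 genes at an unadjusted p under 0.05, and the smallest adjusted p was 0.537, for the deubiquitinase OTUB2 (−1.17, SE 0.26), the reductase MTARC2 (−0.91, SE 0.21) and ENSSSCG00000006793 (0.73, SE 0.17).

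By list, 7 of 10 erythroid markers passed as higher in enriched sows at G98 adjusted over the list alone (median 2.12, camera adjusted p = 0.0115, adjusted p = 0.808 with an estimated correlation), with HBB at 2.67 (SE 0.83, adjusted p = 0.611 over all genes) and AHSP at 2.72 (SE 0.78, adjusted p = 0.611). In 4 enriched R1 libraries at G98 the 10 most abundant genes took 18.1% to 28.6% of the counts, against at most 11.7% in the other G98 libraries, and the erythroid share given above was highest in R1 at G98. Ribosomal protein, cell cycle, nuclear oxidative phosphorylation, endoplasmic reticulum stress and heat shock genes were called as higher by camera and interferon-stimulated genes as lower, all with medians of at most 0.20 in size. With the replicate as a block the interferon list ended its call (adjusted p = 0.0618) and immediate early genes gained one (0.0201). At L11, cell cycle genes were called as higher, and nuclear oxidative phosphorylation, mitochondrially encoded, heat shock, immediate early, complement, ribosomal protein and MHC class II genes as lower. None of the 7 lists at G98 or of the 8 at L11 passed with an estimated correlation, at adjusted p = 0.728 to 0.808 with an estimated correlation at G98 and 0.251 to 0.783 at L11. The library of high C1QA is from a conventional sow, and C1QA was at −3.25 (SE 1.34, adjusted p = 0.808) in enriched sows at L11.

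Whether the change from gestation to lactation differed between groups was tested as an interaction, with a separate paired fit for each factor. By edgeR 0 genes were called for housing, parity and dominance. The numbers at an unadjusted p under 0.05 were 890, 269 and 372, and DESeq2 called 5, 0 and 0. For housing, the smallest p were those of the survival factor MCL1 (−0.41, SE 0.08, adjusted p = 0.182), BATF3 (−0.68, SE 0.15, adjusted p = 0.386) and the transcriptional inhibitor HEXIM1 (−0.34, SE 0.08, adjusted p = 0.386). A negative value is a lower change from G98 to L11 in enriched sows. For parity they were those of EGF (−1.07, SE 0.29), BRMS1L (−0.52, SE 0.15) and MTBP (0.57, SE 0.17), each at adjusted p = 1.00. For dominance they were those of ZBTB1 (−0.47, SE 0.11), SCRN2 (0.72, SE 0.17) and ENSSSCG00000013471 (−0.88, SE 0.23), also at adjusted p = 1.00. Camera called 10 lists in each, 10, 10 and 3 with the replicate as a block, where for housing MHC class II genes replaced B cell markers and for parity interferon-stimulated genes did. None passed with an estimated correlation, the smallest values being adjusted p = 0.111, 0.363 and 0.846 with an estimated correlation.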

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

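The tests of T cell share, of the experimental replicate and of dominance rank for the gamma delta genes, of the library series, and of the stromal covariate and of gene length for each stage or list alone were chosen after the results were seen, and the others before.

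Genes that mark gamma delta T cells were lower in HP than in LP sows, SOX13, BLK and GATA3 at G98 and SOX13 and BLK at L11, where GATA3 passed with the replicate as a block (adjusted p = 0.00432). A lower share of all T cells is argued against by the 13 T cell markers, whose medians were positive, 0.108 at G98 and 0.162 at L11. Their SE of 0.0474 and 0.0475 is taken over the 13 genes. It holds no spread between sows, so the medians were not tested over sows. The experimental replicate is argued against by the design. At G98 R1 held 7 LP and 7 HP libraries and R2 8 and 6, and at L11 each held 7 and 7. With the replicate as a block the called members passed at adjusted p = 0.00432 or less, but this balance left that fit little room to fail. Library depth is argued against by the called members' adjusted p = 0.00683 or less with the total count as a covariate. Dominance rank cannot be told apart from parity, because few sows are dominant and LP or subordinate and HP: with both in the fit at least 0.696 of the log2 fold change was left, SOX13 at G98 went from −1.21 (SE 0.22) to −0.89 (SE 0.26) beside −0.75 (SE 0.33) for dominance, and the calls ended as the fold shrank and its error grew. BLK is also a B cell gene, and IL23R (0.36) had a positive value at G98, so the list does not move as a whole. A lower share of gamma delta T cells with parity, or with rank, may account for the fall, which is a hypothesis, as cell counts were not analysed here.

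In R2 libraries 22 of the inflammatory and immediate early genes were higher than in R1 at G98 and 24 at L11. Their medians, over these higher genes alone, were 1.32 and 1.48. Over all measured members the inflammatory median was 0.647 at G98 and 1.40 at L11, and the immediate early median 1.03 and 0.818. At each stage 2 inflammatory genes and 1 immediate early gene were lower. Library depth is argued against by the 95.8% or more of the higher genes that stayed called with the total count as a covariate. Stromal transcripts are argued against at G98, where 100% stayed called with the stromal mean as a covariate, and stay open at L11, where 58.3% did and the median fell to 0.99, since the stromal genes themselves differ between the replicates. Different animals stay open as well: the 2 sows with an L11 library in both replicates had a median difference of 0.467 and 1.03, against 1.64 in the other 24 L11 libraries, and 2 sows are too few to decide. No biological explanation was tested, as the labels give none for the replicate, and a difference in the handling of the cells could not be examined.

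Nuclear oxidative phosphorylation and ribosomal protein genes rose from G98 to L11, by medians of 0.39 and 0.34. The medians were 0.149 and 0.108 within R1 and 0.654 and 0.624 within R2, and neither list passed with an estimated correlation. Both lists hold short genes (median length 1450 and 1160 bases, against 3120 over all genes), and across genes, which are not independent, log2 fold change fell with length (Spearman rho −0.252). Gene length is argued against as the whole cause for the oxidative phosphorylation list, whose median lay at percentile 100 of 10000 lists matched on length and expression. It stays open for the ribosomal list at percentile 96.83. The matched lists rose too, with medians centred on 0.136 and 0.231, so part of each rise was shared with other genes of like length and expression. Their members were drawn singly, so the percentiles leave out correlation between the genes of a list. Haemoglobin transcripts taking up counts would give the larger rise in R1, where HBB fell more (−4.58, against −0.81 in R2). Both lists rose less in R1, which argues against haemoglobin as the whole cause. With HBB as a covariate 143% and 137% of the medians were left. That covariate partly follows the replicate, so these percentages alone do not decide the question. The library series stays open, because 0 libraries have a code of the series used at the other stage, so a technical difference between the series may account for the rise as well as lactation may, which was not tested.

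The rise or fall from G98 to L11 differed between R1 and R2 for 2576 genes by the test of the difference, and for 10 of the named genes. The fall was smaller in R2 for DMTN (by 2.68 on the log2 scale, SE 0.66), AHSP (3.43, SE 0.82), HBB (3.75, SE 0.92), HBM (3.22, SE 0.81) and SNCG (3.15, SE 0.78). The rise was larger in R2 for NDUFB1 (by 0.581, SE 0.15), CYCS (0.559, SE 0.12), RPL36A (0.385, SE 0.12), RPL27 (0.585, SE 0.12) and RPS15A (0.732, SE 0.14).

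Of 30 groups tested for a single library far from the others, 3 had 1, where chance gives about 1 in 20 groups, or 1.5. L1CAM was at 11.11 CPM in an intermediate sow at L11, against 3.455 to 6.995 CPM in the other libraries of 9. The total count was 20624978 in a conventional LP subordinate library at G98, against 22019165 to 22421783 in the others of 5. The 10 most abundant genes took 17.7% of the counts in a conventional LP subordinate library at L11, against 6.69% to 9.48% in the others of 5.

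Whether other splits of the sows into groups of the same sizes give as many genes was tested with 100 random splits for each comparison within a stage and 40 for the paired fits. Chance is argued against for parity at G98 (180 genes, at most 26 in another split, as large in 1 of 100, the real split itself). The same holds for stage (6990, at most 2091, 1 of 40). For parity at L11 (22, at most 74, 3 of 100) other splits gave as many or more, so chance is not excluded there. The splits at L11 moved single libraries, so the repeat libraries of a sow were treated as separate animals. Chance is also not excluded for housing at G98 (1, at most 115, 6 of 100). The counts of 0 for housing at L11 (at most 560), dominance at G98 (at most 1) and L11 (at most 1248) and the interactions of stage with housing (at most 0), parity (at most 386) and dominance (at most 344) are reached by each split. With splits drawn within each experimental replicate, no other split gave as many for housing at G98 (at most 0), parity at G98 (at most 0) and parity at L11 (at most 1). Each was as large in 1 of 100, the real split itself, which argues against chance within the replicates, with the same limit on the repeat libraries at L11. Some splits called 115, 560, 1248, 386 and 344 genes, where the groups called 1 or 0. For housing at G98 the highest count fell from 115 to 0 with splits within each replicate. For the others such splits were not run, and the cause of their high counts was not tested.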

How the results depend on the processing

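Of 121 alternative counts of genes or lists, 77 stayed within 1.5 times the reported count, among them every one for stage (5263 to 7793 genes, against 6990) and for housing at L11 (0 in each). The fits with all 3 factors and the replicate block, with a replicate by stage term, with HBB as a covariate and without the library of high C1QA were chosen after the data were seen. At a threshold of 0.1, parity gave 491 genes at G98 and 47 at L11 and dominance 112 and 8. DESeq2 called 3 genes for housing at G98, 459 and 61 for parity, 218 and 59 for dominance and 5 for the stage by housing interaction. The replicate block gave 357 and 37 genes for parity and 3 for dominance at L11, and 3 lists for the stage by dominance interaction, and moved no other count by more than 1.5 times. With all 3 factors in the fit, with or without the replicate block, parity gave 2 genes at G98 and 0 at L11, where part of the parity difference is shared with dominance by design. Limma voom over both stages called 0 genes for housing, 114 for parity and 30 for dominance at G98 and 13 for dominance at L11, and without the repeat libraries of 2 sows parity at L11 gave 12. With an estimated correlation 1 list (gamma delta genes, parity at L11) was called over all comparisons and 0 in each other, also with a replicate by stage term. Fry called 0, 1 and 2 lists at G98 for housing, parity and dominance, 0, 1 and 2 at L11, 22 for stage and 1, 0 and 0 for the interactions. Where not stated, the cause was not tested.

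Leaving out each sow gave 52 to 581 genes for parity at G98, 7 to 42 for parity at L11, 0 to 161 and 0 to 32 for dominance, 6793 to 7013 for stage, 1 for housing at G98 each time and 0 for housing at L11 and the interactions. For parity at G98, counts over 1.5 times off were 52 without sow T82166, 87 without T83868, 91 without T454, 95 without T93287, 97 without T83821, 102 without T382, 107 without T82133 or T83859, 113 without T82157, 115 without T91645, 116 without T93157, 117 without T408, 118 without T83410, 271 without T91384 and 581 without T91919. For parity at L11 they were 7 without T93287, 8 without T82157, 10 without T93220, 11 without T82166, T91403, T93157 or T93204, 12 without T83859, 13 without T619 or T83868, 14 without T82133, 37 without T93120 and 42 without T91533. For dominance at G98 they were 14 without T91533, 22 without T408, 31 without T91645, 35 without T82157, 42 without T91384 and 161 without T83888, and at L11 1 without T93120, 5 without T382, 8 without T91645, 11 without T91384 and 32 without T91533.

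Of 58 named calls, 45 passed without each sow in turn. The other 13 had a largest adjusted p of 0.0565 for F2RL1 (without sow T83888), 0.0620 for IL1RL2 (T83859), 0.0675 for ANK2 (T82166), 0.0752 for CD163 (T454), 0.0637 for SLC6A17 and 0.0935 for PAMR1 (T382) at G98, 0.0664 for VWA5A, 0.0996 for ACVR2A and 0.148 for LZTS1 (T82133), 0.0986 for BATF3 (T83888), 0.0521 for IL9R (T93287) and 0.0740 for RHEX (T93220) at L11, and 0.0779 for COL3A1 (T91645). All 3 factors ended 27 of 29 calls of the single-stage fits, with CUX2 and AHRR still called at G98. With HBB as a covariate, HBB itself went to 0.000309, as the covariate removes it, and SNCG from −2.10 to 0.162 (adjusted p = 0.0436). AHSP (adjusted p = 0.0966) and HBM (0.158) lost their calls, and no other named call for stage changed in that fit. Depth limits mainly genes near 1 CPM, which have 18.1 to 25.3 counts in a library.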

Other observations

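The tests and genes of this part, among them the comparison of R2 with R1 and the stromal list, were chosen after the values were seen. Early activation genes were higher in R2 libraries at both stages, with 14 libraries in each replicate. The NF-kB inhibitor TNFAIP3 was at 111 ± 91.6 CPM in R1 and 737 ± 248 in R2 at G98 (log2 difference 2.80, SE 0.25) and at 175 ± 59.9 and 1080 ± 324 at L11 (2.61, SE 0.17). The activation marker CD83 was at 10.9 ± 2.92 and 71.2 ± 26.6 CPM at G98 (2.67, SE 0.16) and at 17.1 ± 3.38 and 186 ± 87.4 at L11 (3.43, SE 0.20). The nuclear receptor NR4A1 was higher by 2.48 (SE 0.23) and 2.84 (SE 0.24), IER3 by 3.56 (SE 0.48) and 2.62 (SE 0.38) and G0S2 by 3.17 (SE 0.38) and 3.58 (SE 0.33). FOS did not follow, at 0.39 (SE 0.20, adjusted p = 0.133) and 0.0036 (SE 0.16, adjusted p = 0.988). Of 16 immediate early genes 12 were higher and 1 lower in R2 at each stage, and of the inflammatory list 10 of 16 were higher at G98 and 12 of 17 at L11, with 2 lower at each stage, at adjusted p = 0.486 and 0.421, and 0.638 and 0.440, with an estimated correlation.

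Stromal genes were higher in R2 at L11 in 11 of 11 measured (median 2.80, adjusted p = 0.421 with an estimated correlation). COL1A1 was at 9.38 ± 14.8 CPM in R1 and 56.2 ± 66.3 in R2 (2.77, SE 0.75, adjusted p = 0.00375), COL3A1 was at 8.51 ± 12.7 and 65.7 ± 82.8 (3.01, SE 0.68) and DCN was at 2.78 ± 4.57 and 18.6 ± 13.9 (2.84, SE 0.59). At G98 the median was 1.71 and 0 of 11 passed. Ribosomal protein genes were higher in R2 at L11 in 46 of 48 and lower in 1 (adjusted p = 0.421 with an estimated correlation), and at G98 7 were higher and 10 lower (0.991).

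The libraries carried a signature of the individual sow. After stage and replicate means were taken out, a library correlated best with the library of the same sow at the other stage in 38 of 52 cases over the 100 most variable genes, 47 over 200, 52 over 500, 51 over 1000, 50 over 2000 and 49 over 5000. In 200 shuffles of the ear tags, over 500 genes, the median was 2 and the highest 6. Among the L11 libraries of R1, those of the same sow correlated best with the R2 library of sow T82133 and with that of sow T82157.

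In a single L11 library of R2, from a conventional HP dominant sow, several genes of the complement and monocyte lists stood far above the 27 other L11 libraries. C1QA was at 471 CPM (highest other 5.97), C1QB at 504 (6.48), C1QC at 546 (6.86), CD163 at 2000 (227) and the scavenger receptor MARCO at 39.9 (1.59). S100A8 was at 775 (115), S100A12 at 1290 (150), CD14 at 429 (139) and CD68 at 192 (52.1). LYZ was at 1180 (833), and the transglutaminase TGM3, of neither list, was at 2630 (580).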
